A study of Rosa chinensis with 4 samples.

How the data were processed

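ChIP-seq was done on petals of Rosa chinensis at the onset of flower opening, with antibodies against H3K9ac and H3K27me3 and an input for each, giving 4 samples of 1 library. Groups were taken from the labels. The H3K9ac library was analysed through its peak lists on 2 assemblies, and the other 3 samples were not analysed here. The peak names inside the lists hold the word flower, whereas the labels say petal, and the labels were followed.

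The submitters' processing notes name FastQC, Trim Galore, Bowtie2, MACS2 and SICER, and their versions, settings and order are not given in the sources used here, nor is the handling of duplicate reads or of reads with several matching places. The lists have the column layout that MACS2 writes. Peaks were called on the single H3K9ac library and not on pooled samples, per the labels, which list 1 such library. The score column of the deposited lists was, from its values, the whole part of 10 times the −log10 q-value. This held for 100% of the RcHzRDP12 peaks and 99.996% of the RchiOBHm peaks. The fold enrichment deposited by the authors is a linear ratio of fragments at the summit to the local background, with 1 added to both. The p-value and q-value of each peak were deposited as −log10 values. The lowest −log10 q-value was 1.33 on RcHzRDP12 and 1.31 on RchiOBHm, so a q-value threshold of 0.05 was read from the values. Such values measure how far the fragments of this library exceed its background and hold no spread between plants. The start was deposited as a position counted from 0 and the summit as an offset from the start. All coordinates are given here counted from 1, which leaves the deposited end unchanged.

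No read totals are stated in the lists. Depth was therefore recovered from each peak: given the fold enrichment and a Poisson p-value, 1 whole number of fragments and 1 background reproduce both. Within a tolerance of 0.002 in the −log10 p-value this gave a whole number for 50543 of 50543 peaks on RcHzRDP12 and 46594 of 46596 on RchiOBHm. On simulated peaks, 100% of 4936 pileups were recovered. The lowest background was 3.24 fragments on RcHzRDP12 and 3.07 on RchiOBHm, and 75.0% and 19.9% of the peaks stood on it. Local backgrounds moved in steps of 0.300 and 0.276 fragments. Read as the scaling of the input to the ChIP library, these steps correspond to 3.34 and 3.62 input fragments per ChIP fragment. Intervals of fold values are exact Poisson intervals on the summit fragments. The shortest peaks, 145 and 142 bp, were taken as the fragment length, and the highest pileup came to 290 and 282 fragments, at or just under the 290 and 284 that 1 fragment per position and strand allows.

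Genes came from the RefSeq table of the assembly RchiOBHm-V2, with 41273 genes, of which 41022 lie on the 7 chromosomes and 30798 of these are protein-coding. The match of this build to the RchiOBHm list was checked on the data. On the 7 chromosomes, 28.2 to 33.8% of protein-coding gene ends had a summit within 500 bp in place, and 8.66 to 11.8% after a shift of 20 kb. The RcHzRDP12 peaks were described by number, width and height only. Coordinates were not converted between assemblies, and peaks were not paired between them.

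Each summit was placed in the first class that applied: inside a protein-coding gene within 1 kb of an end, deeper inside, inside another annotated gene, outside within 1 kb of a gene, or farther. The control was 1000 random placements of the peaks along the same chromosome, which did not leave out unknown bases. The profile around ends, the median distance and the classes of gene density used 100 placements. A gene was marked when a peak overlapped by at least 1 bp the window from 500 bp outside to 1000 bp inside either end. Other gene types were set beside 200 sets of positions matched on length and on distance from protein-coding genes, and 20 sets were used where this difference was recomputed under other settings. The class assignment was checked on uniformly simulated summits, of which 10.7% fell at gene ends against 10.6% expected, and after moving summits to gene ends, 54.8% against 55.3%. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

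The plan made before the data were examined assumed transcription start sites, exons, product names and a genome sequence. The table used here has no strand, exons or product names, and no genome sequence was used. Start-site windows were therefore replaced by windows at both gene ends. The planned gene lists by product name, such as scent and anthocyanin enzymes, the classes of exons and untranslated regions, and the GC and repeat content of peaks were not analysed. Genes are named by identifiers because only the 498 tRNA genes have other symbols. The rule for named genes was reduced to the 10 protein-coding genes with the highest fold of a peak in a window, and the genes under the 5 widest peaks. The 10 peaks of highest fold, the limit of 3 kb on gene length, the inner 1 kb end zones, the distances of 5 and 10 kb and the classes of summit fragments were chosen after the data were seen. Results were recomputed with a −log10 q-value of at least 10, a fold of at least 5, peak midpoints, other windows and overlaps, merged peaks and 500 kb windows. Control positions matched on length and gene density, but not on distance from protein-coding genes, were also used.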

Results

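The series profiled histone modifications in petals of the China rose, Rosa chinensis, at the onset of flower opening, with the aim of giving a view of the rose epigenome. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with 1 antibody against H3K9ac, an acetylated form of histone H3 that in plants is found around the start of transcribed genes, and 1 against H3K27me3, a methylated form associated with silenced genes. Each antibody had its own input, so the labels list 4 samples of 1 library each. The deposited peak lists of the H3K9ac library were used here, and the H3K27me3 library and the inputs were not analysed here. The same library had been placed on 2 assemblies, named RcHzRDP12 and RchiOBHm by the authors. There were no replicates, so no test across samples was possible and no p-values are given. Intervals are 95% exact binomial or Poisson intervals, and those on ratios of peak counts use a normal approximation on the log scale. They cover counting error only, and peaks and genes are not independent replicates. The depth behind a peak was read from the number of fragments over its summit, recovered from the deposited fold enrichment and p-value. The median was 23 fragments on RcHzRDP12, with a range of 10 to 290, and 22 on RchiOBHm, with a range of 9 to 282.

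H3K9ac in petals was called as many narrow, separate peaks on either assembly. On RcHzRDP12 there were 50543 peaks covering 26.2 Mb, and on RchiOBHm there were 46596 covering 27.01 Mb. The median peak was 448 bp wide on RcHzRDP12 and 446 bp on RchiOBHm, and no peaks overlapped within a list. The median fold enrichment over the local background, the authors' own value for each peak, was 5.35 on RcHzRDP12 and 4.67 on RchiOBHm. The RcHzRDP12 peaks were spread over 7088 sequences, with a median of 3 peaks per sequence. The RchiOBHm peaks lay on 36 sequences, namely 7 chromosomes with 46391 peaks, 28 unplaced sequences with 139 peaks and a sequence named CP with 66 peaks.

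The ratio of peak counts between the assemblies turned with the height of the peaks. Up to their last peaks, the sequences with peaks spanned 724 Mb on RcHzRDP12 and 508 Mb on RchiOBHm. The counts were not scaled to this length. All peaks together were 1.08 times as many on RcHzRDP12 (interval 1.07 to 1.10). At 40 or more fragments over the summit there were 7878 peaks on RcHzRDP12 and 10749 on RchiOBHm, a ratio of 0.733 (0.712 to 0.755), and at 60 or more fragments the ratio was 0.477 (0.451 to 0.503). At 150 or more fragments the order turned again, with 154 peaks on RcHzRDP12 and 95 on RchiOBHm, a ratio of 1.62 (1.26 to 2.09). The intervals treat both lists as independent counts, although both come from the same fragments. At a −log10 q-value of at least 10, the counts were 24776 and 21272, and at a fold enrichment of at least 5 they were 27285 and 21668.

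**Figure D1:**
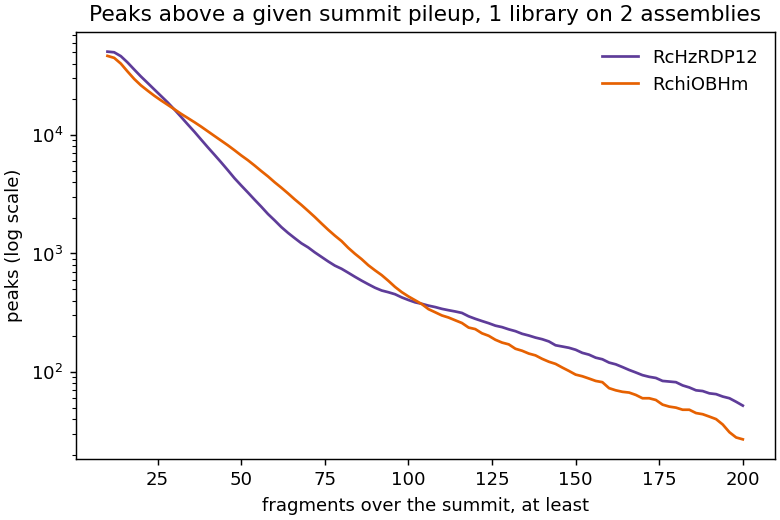
Number of H3K9ac peaks (y axis, log scale) with at least a given number of fragments over the summit (x axis), for the same petal library on the assemblies RcHzRDP12 and RchiOBHm. The RcHzRDP12 line lies above at 20 fragments (31186 against 26255 peaks), below at 60 (1902 against 3991) and above again at 150 (154 against 95).

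Acetylated regions were concentrated at the ends of protein-coding genes. On the 7 chromosomes of RchiOBHm, 22813 of 46391 summits (49.2%, interval 48.7 to 49.6) lay inside a protein-coding gene within 1 kb of one of its ends, 4.66 times the mean share of 10.6% among 1000 random placements of the peaks. The space more than 1 kb from any annotated gene held 8426 summits (18.2%, 17.8 to 18.5) against 59.3% at random, a ratio of 0.306. The placements did not leave out unknown bases, and the handling of reads with several matching places is not known. Both ratios may therefore include differences in where reads could be placed. Gene interiors deeper than 1 kb held 6775 summits (14.6%, 14.3 to 14.9), slightly above the 11.9 to 12.8% of the random placements, and genes of other kinds held 4015 (8.65%) against 5.79%. Peaks at gene ends were also wider and higher, with a median width of 628 bp and a median fold enrichment of 5.94, against 290 bp and 3.69 for peaks deeper in genes. When peaks were ranked into 10 classes by fold enrichment, 35.5% lay at gene ends in the lowest class and 77.6% in the highest, at a fold of 12.1 or more. The share deeper inside genes went the other way. It fell from 25.7% in the lowest class to 4.01% in the highest, which is below the random range.

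Summits were displaced from the gene end into the gene body. Around the 28160 ends of the 14080 protein-coding genes of at least 3 kb, the most populated 100 bp stretch lay 200 to 300 bp inside the gene, with 2982 summits, 11.5 times the random mean. The stretch 300 to 400 bp inside held 2618 summits (10.1 times), while the 100 bp just outside the end held 259 (0.997 times). Farther outside, from 800 to 900 bp, there were 552 summits (2.11 times). The median distance from a summit to the nearest protein-coding gene end was 715 bp, against a mean of medians of 4109 bp over 100 random placements. The annotation table carries no strand, so transcription starts and ends were not separated.

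**Figure D2:**
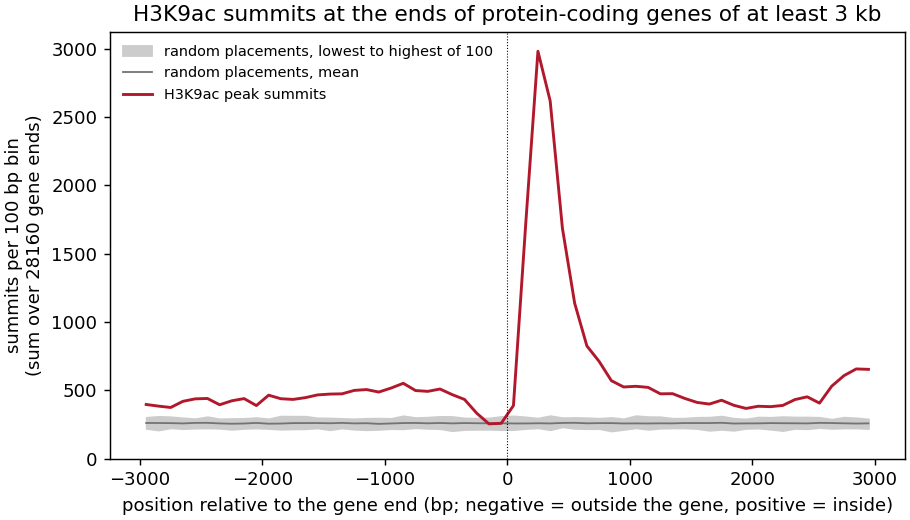
Peak summits per 100 bp (y axis) by position relative to the gene end (x axis, bp, positive values inside the gene), summed over 28160 ends of protein-coding genes of at least 3 kb. The red line is the H3K9ac library and the grey band spans the lowest to highest of 100 random placements; the maximum of 2982 summits lies 200 to 300 bp inside.

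At the authors' threshold, H3K9ac lay at an end of more protein-coding genes than random placement of the peaks gave. A gene was called marked when a peak overlapped, by at least 1 bp, the stretch from 500 bp outside to 1000 bp inside either end. By this measure 19132 of 30798 genes were marked (62.1%, 61.6 to 62.7), against a mean of 28.4% over random placements, whose highest value was 29.2%. The share fell to 45.8% at a −log10 q-value of at least 10 and to 46.5% at a fold of at least 5. Of all genes, 10080 (32.7%) had a peak at 1 end, 9052 (29.4%) at both and 11666 (37.9%) at neither. In short genes the windows of both ends overlap, so 1 peak can count for both. In genes of at least 3 kb, where the inner 1 kb of both ends are separate, 7802 of 14080 (55.4%) held a summit at 1 end only, against 47.9 to 50.7% when the end states were shuffled between genes. Both ends held a summit in 2224 (15.8%), below the shuffled range of 18.2 to 19.6%.

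Marking varied with gene length. In the shortest of 10 length classes of protein-coding genes, 114 to 897 bp, 26.2% were marked (24.6 to 27.8), against 18.5% at random. The share was 65.1% (63.4 to 66.8) for genes of 2270 to 2767 bp and reached 81.3% (79.9 to 82.7) for genes of 5076 to 7099 bp, against 31.8% at random. For the longest class, of 7100 bp or more, it was 71.6% (70.0 to 73.2). Very short gene models lie wholly within the windows, so the random share is the value to set beside each.

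The most enriched peaks at protein-coding gene ends had folds of 28.8 to 31.4 over background. Coordinates are on RchiOBHm-V2. The highest fold at a protein-coding gene, 31.4 (26.3 to 37.2, with 131 fragments at the summit), belonged to LOC112173683 on chromosome 6 from 66993007 to 66995263, with the summit 226 bp inside the nearer end. LOC112181555 on chromosome 1 from 47872198 to 47877696 followed at 30.7 (25.6 to 36.6), with its summit 176 bp inside, and LOC112197003 on chromosome 4 from 59239834 to 59241581 also had 30.7 (25.6 to 36.6). LOC112176786 on chromosome 7 from 3811200 to 3814917 had 29.8 (25.1 to 35.3). A single peak of fold 29.6 touched the windows of the neighbours LOC112178678 and LOC112178679 on chromosome 7, with its summit inside LOC112178679. Another of fold 29.5 was shared by LOC112200024, LOC112200435 and LOC112200436 on chromosome 4, with its summit inside LOC112200436. LOC112199560 on chromosome 4 had 28.8, with the summit outside the gene, which runs from 53776771 to 53777277. The intervals of all 10 genes overlapped, so their order was not resolved at this depth.

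The widest regions of acetylation extended over most of the length of the genes beneath them. On chromosome 2, a peak from 8472307 to 8478213 (5907 bp, fold 16.4) covered 5250 bp of the 5586 bp of LOC112190746. Also on chromosome 2, a peak from 85737319 to 85743135 (5817 bp, fold 12.7) covered 4417 bp of the protein-coding LOC112185351 and all of LOC112185352, a long non-coding RNA (lncRNA) gene. LOC112170364 on chromosome 6 lay under a peak from 57013940 to 57019213 (5274 bp, fold 15.03), which covered 4931 bp of its 5050 bp. LOC112196997 and LOC112196994 on chromosome 4 shared a peak from 51517631 to 51522608 (4978 bp, fold 13.6), which covered LOC112196997 whole and 1669 bp of the 2788 bp of LOC112196994. The widest peak of all, 11724 bp on chromosome 3 from 49725554 to 49737277, spanned 3 ribosomal RNA genes, LOC112195624 (3393 bp), LOC112195544 (156 bp) and LOC112195621 (1808 bp), at a fold of 3.56, with 282 fragments over its summit and a local background of 78.4. Both lie at or just under the highest values that 1 fragment per position and strand allows. This caps the fold there at 3.59, so its enrichment could not be measured.

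The 10 highest peaks genome-wide lay mostly away from protein-coding gene ends, a list chosen after its values were seen. Of the 10 peaks with the highest fold enrichment, 1 was at a protein-coding gene end, 4 had their summits inside lncRNA genes and 4 lay more than 1 kb from any gene. Among the 100 peaks with the highest fold, protein-coding gene ends were the most frequent location, with 44 peaks, followed by 34 more than 1 kb from any gene. The highest, on chromosome 2 from 33528297 to 33529025, had a fold of 42.3 (36.5 to 48.9) and lay 13446 bp from the nearest gene. The lncRNA genes were LOC112180261 (fold 40.4) and LOC121050857 (39.8) on chromosome 7, LOC112195014 (38.5) on chromosome 3 and LOC121049897 (35.1) on chromosome 6. The share of peaks at protein-coding gene ends rose from 39.1% at 9 to 19 fragments over the summit to 77.6% (76.0 to 79.1) at 60 to 79, then fell to 3.45% (0.717 to 9.75, 3 of 87 peaks) at 150 or more. In the same classes the share more than 1 kb from any gene was 18.9%, 8.78% and 63.2% (52.2 to 73.3).

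**Figure D3:**
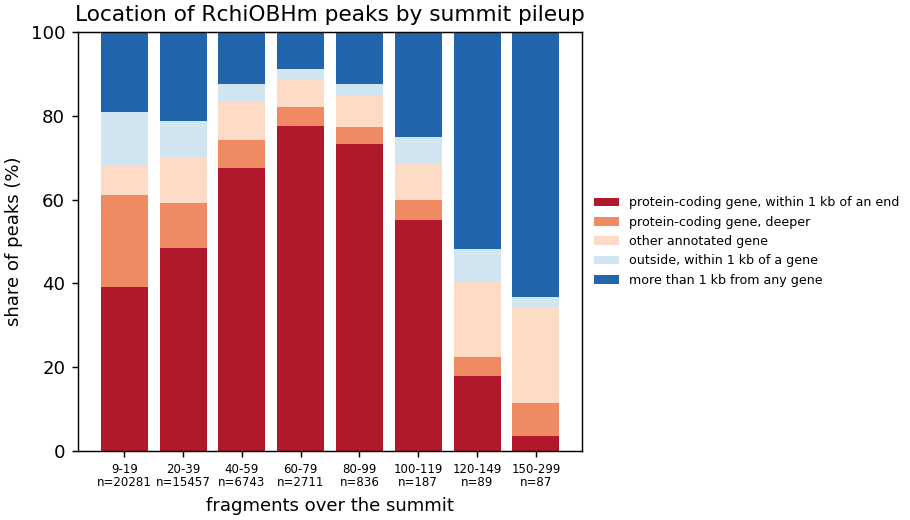
Share of RchiOBHm peaks (y axis, %) in each location class, by number of fragments over the summit (x axis, number of peaks under each bar). Peaks at protein-coding gene ends make up 77.6% of those with 60 to 79 fragments and 3.45% of those with 150 or more, where 63.2% lie more than 1 kb from any gene.

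Genes other than protein-coding ones carried the mark to different extents. Of 6193 lncRNA genes, 2575 (41.6%, 40.3 to 42.8) were marked, against 13.8 to 16.03% over 200 sets of control positions of like length and distance from protein-coding genes. Of 498 tRNA genes, whose products carry amino acids to the ribosome, 236 (47.4%, 42.9 to 51.9) were marked against 20.1 to 29.9% at control positions. Of 451 snoRNA genes, which guide the modification of ribosomal RNA, 166 (36.8%, 32.3 to 41.4) were marked against 9.98 to 19.1%. Pseudogenes were marked in 859 of 2585 cases (33.2%, 31.4 to 35.1, control 15.2 to 19.1%). Of 263 rRNA genes, 12 were marked (4.56%, 2.38 to 7.83), inside the control range of 1.52 to 10.3%. The marked ones include the 3 under the widest peak, whose enrichment could not be measured. The handling of reads with several matching places is not known, so few peaks here need not mean little acetylation. These rRNA genes were mostly of 119 bp, 110 of them on chromosome 1 and 107 on chromosome 3.

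The excess at lncRNA genes was also present far from protein-coding genes. More than 5 kb from any protein-coding gene, 1013 of 2816 lncRNA genes were marked (36.0%, 34.2 to 37.8), against 6.29 to 8.84% at control positions. For tRNA genes at that distance it was 8 of 54 (14.8%, 6.62 to 27.1), above the 0 to 11.1% of the control sets but with an interval that reaches into their range. For snoRNA genes at that distance it was 15 of 157 (9.55%, 5.45 to 15.3), against 0 to 8.92%, again with an interval that reaches into the control range. Of all snoRNA genes, with a median length of 106 bp, 28.2% overlapped a protein-coding gene, so a peak in their windows can belong to another gene. The share for snRNA genes, whose products act in splicing, was 25.4% (33 of 130, 18.2 to 33.8) against 7.69 to 23.1%, and its excess turned from 10.5 to −1.58 percentage points at a −log10 q-value of at least 10. Such recomputed excesses used 20 control sets, so they can differ slightly from those over 200. At that q-value the excess went from 26.6 to 19.1 percentage points for lncRNA genes, from 16.2 to 7.49 for pseudogenes and from 22.7 to 14.5 for tRNA genes. Other control positions were matched on length and regional gene density, but no longer on chromosome or distance from protein-coding genes. Against these the excess was 19.1 for lncRNA genes, 9.05 for pseudogenes and 30.3 for tRNA genes. It fell from 25.1 to 14.1 for genes typed as misc_RNA, and went from −0.418 to −5.30 for rRNA genes. Because the match on distance was dropped, a rise such as that for tRNA genes does not show a stronger excess. By amino acid, marking of tRNA genes ranged from 29.2% (7 of 24 glutamine tRNA genes) to 63.2% (12 of 19 threonine tRNA genes), with overlapping intervals.

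**Figure D4:**
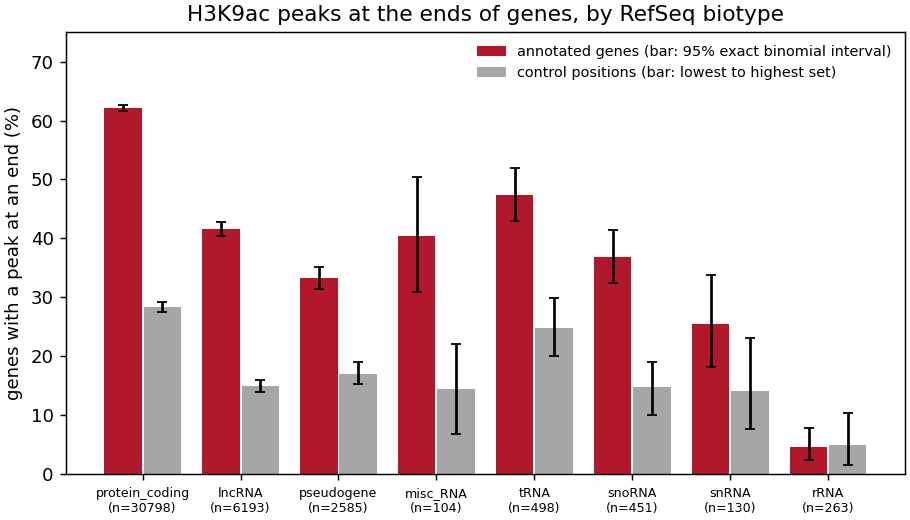
Percentage of genes with an H3K9ac peak at an end (y axis) for each gene type of the annotation (x axis, number of genes in brackets). Red bars are the annotated genes with 95% exact binomial intervals; grey bars are control positions with the lowest to highest set, which are random placements of the peaks for protein-coding genes and matched positions for the others. The shares are 62.1% for protein-coding, 41.6% for lncRNA and 4.56% for rRNA genes.

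Along the chromosomes the mark followed the genes. Chromosome 2 had the highest density, 98.0 peaks per Mb (95.9 to 100.1), and chromosome 5 the lowest, 84.5 (82.6 to 86.4). The share of marked genes was 66.0% (64.8 to 67.3) on chromosome 2 and 57.9% (56.6 to 59.3) on chromosome 5, and the random shares moved with it, at 30.1% and 26.0%. Relative to random the values were 2.19 and 2.23. Over 500 windows of 1 Mb, the number of peaks and the number of protein-coding genes had a Pearson correlation of 0.910 and a Spearman correlation of 0.878, and within single chromosomes Pearson values ran from 0.865 to 0.943. Neighbouring windows are not independent, so no p-value is attached. The richest window was the first Mb of chromosome 5, with 239 peaks and 131 protein-coding genes, followed by chromosome 6 from 62000001 to 63000000 with 229 peaks. Chromosome 3 from 42000001 to 43000000 held 2 peaks and 4 protein-coding genes, and chromosome 5 from 49000001 to 50000000 held 2 peaks and 1 gene.

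The share of marked genes was higher in gene-rich regions, and so was the share that random placement of the local peaks gave. When the windows were ranked into 4 classes by gene number, the share of protein-coding genes with a peak at an end was 51.1% (49.6 to 52.6) in the class with the fewest genes. It was 56.1% and 59.4% in the middle classes and 70.8% (69.9 to 71.6) in the class with the most genes. The median number of peaks per window rose from 50 to 148 over the same classes. Placing each peak at random within its own window, a control added after the data were seen, gave a mean of 17.6% in the class with the fewest genes and 42.9% in that with the most, over 100 placements. Placement along the whole chromosome gave 28.2% and 28.7%.

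**Figure D5:**
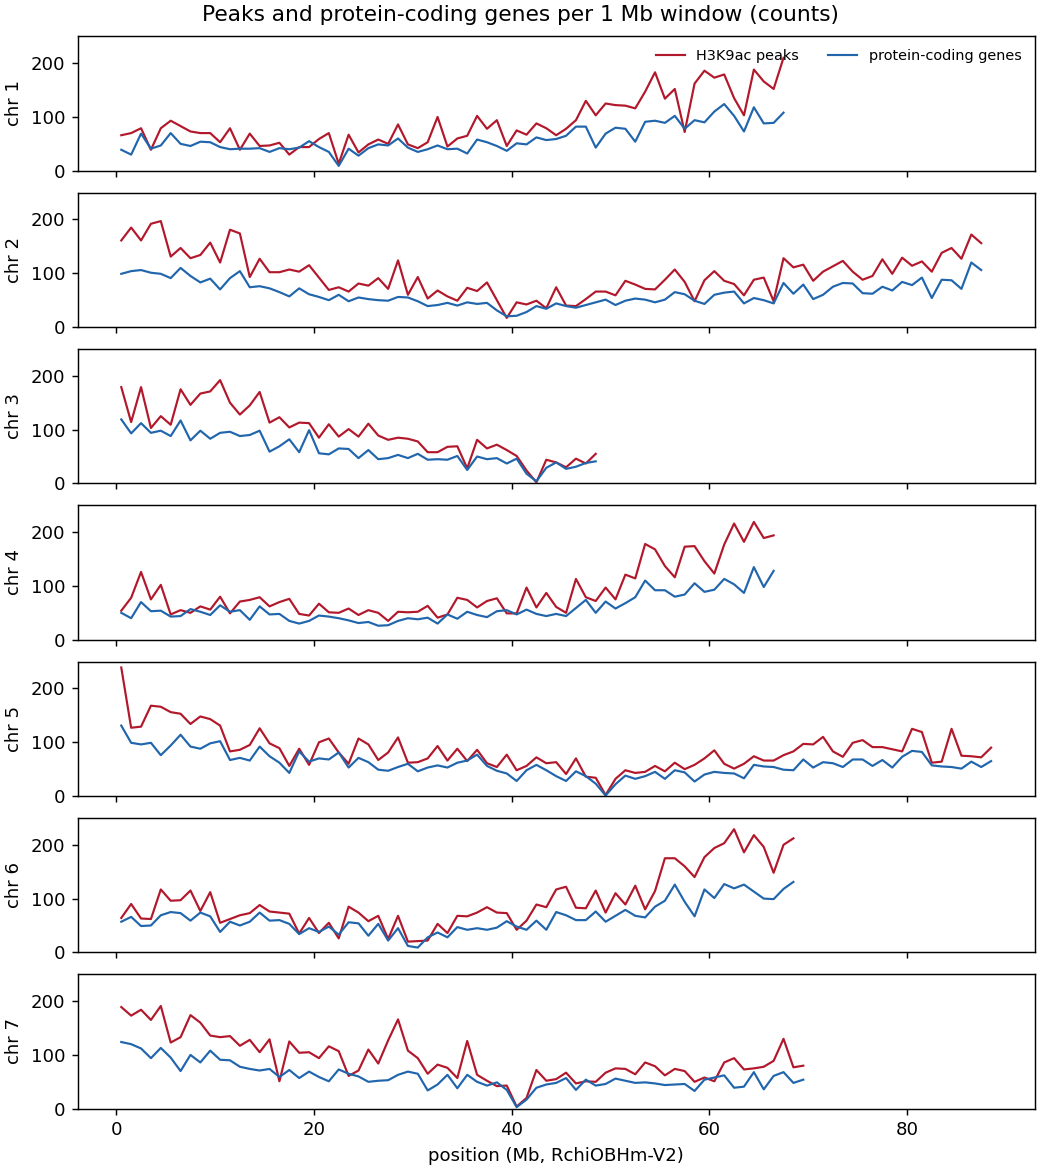
Number of H3K9ac peaks (red) and of protein-coding genes (blue) per 1 Mb window (y axis, counts) along the 7 chromosomes of RchiOBHm-V2 (x axis, Mb). Both lines rise and fall together, from 2 peaks in the poorest windows of chromosomes 3 and 5 to 239 in the first window of chromosome 5.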

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

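The peak counts above a given number of fragments, and the count without CP and unplaced sequences (46391), were chosen after the result was seen. The other alternatives were recorded as planned. Many of them, however, vary measures that were not in the plan, namely windows at gene ends, inner end zones and gene types beside matched positions. Of 38 alternatives to the main results, 13 stayed within the interval, or within 1.5 times for counts and covered lengths, 23 moved and 2 reversed. By this wide limit the covered lengths stayed, although on RcHzRDP12 they fell to 17.7 Mb (q-value) and 18.95 Mb (fold). On RchiOBHm they fell to 18.96 Mb and 19.1 Mb. Peak counts fell at a −log10 q-value of at least 10 to 24776 on RcHzRDP12 and 21272 on RchiOBHm, and at a fold of at least 5 to 27285 and 21668, by construction. The ratio of counts became 1.16 and 1.26 under these thresholds, 1.19 at 20 or more fragments, and reversed to 0.733 at 40 and 0.477 at 60. Summits inside protein-coding genes moved to 68.7% (q-value) and 68.6% (fold). Those within 1 kb of an end became 61.3% and 61.2%, and 48.6% by midpoint, and those more than 1 kb from any gene 15.8% and 15.95%. The median distance to an end was 479 bp (q-value) and 774 bp (midpoint). Marked protein-coding genes were 57.5% with 200 bp of overlap, 59.8% by summit, 63.9% over the gene body, 54.5% within 250 bp of an end, 45.8% (q-value) and 46.5% (fold). The Spearman correlation was 0.828 in 500 kb windows. Apart from the thresholds on counts, the cause was not tested. Of 28 alternatives for other gene types, 18 stayed, 9 moved and 1 reversed, the snRNA excess, which, over 20 control sets, went from 10.5 to −1.58 percentage points at the stricter q-value, where the cause was not tested. Merging could change nothing because no peaks overlapped, so the merged alternatives, counted among those that stayed, do not show stability. Random placement matched on GC, the whole-peak sequence context and lists without same-product neighbours were not run, for lack of sequence and product names. No paired analysis was possible because the peak lists come from 1 library. Called peaks on RchiOBHm had a median of 22 fragments at the summit and went down to 9. Acetylation too weak to reach the threshold lies below what this library resolves.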

Other observations

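The tests on neighbouring genes and on lncRNA ends were written before their results were seen, the latter after some strong peaks in lncRNA genes had been noticed; the tests on CP, the assemblies, the distant high peaks and facing ends were chosen only after the result was seen.

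Protein-coding genes were marked more often after a marked neighbour than after an unmarked one. For successive genes more than 10 kb apart, the next gene was marked in 59.0% of cases after a marked gene and in 47.8% after an unmarked one, a difference of 11.2 percentage points. Shuffling within classes of gene density and length gave at most 5.38 in 1000 shuffles, so these classes do not account for the whole difference. In separate shuffles, however, the shares were 60.2 to 63.4% and 58.6 to 62.8%, both above the observed ones. Genes beside such wide gaps were thus marked less often than the genes from which the shuffles drew. The shuffles did not hold this, so whether the difference reflects domains larger than single genes was not decided. The longest run of unmarked genes had 19 genes on chromosome 5 from 19166534 to 19468923, a stretch that still held 8 summits outside their end windows. Shuffles within classes of gene length and chromosome gave longest runs of 9 to 17, and those within classes of gene density and length 9 to 20. The latter shuffles gave at most 10 runs of 10 or more unmarked genes, with a mean of 4.21, against 47 observed. Adjacent genes can share a peak, which shuffling breaks, so the excess of runs is not by itself evidence of domains.

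Summits also gathered just inside the ends of lncRNA genes. In the 1133 lncRNA genes of at least 3 kb lying more than 1 kb from protein-coding genes, 378 summits fell 100 to 400 bp inside the ends, 5.98 times random placement, against 28 (0.444 times) at the same distance outside and 48 (0.761 times) at 1000 to 1300 bp inside. This is consistent with many of these models being transcription units with their own start, a hypothesis that the missing strand leaves open. For facing ends of neighbouring protein-coding genes, both ends held summits 1.28 times as often as shuffled (1.17 to 1.39) at gaps up to 400 bp and 1.14 times (1.09 to 1.19) at gaps of 5 to 50 kb. The intervals overlap, so a shared start region at close pairs cannot be told apart from a general tendency of neighbours.

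The 66 peaks on the sequence named CP had a median fold of 1.71, against 4.68 on the chromosomes, at a median of 126.5 fragments, and their range of 1.41 to 2.58 overlapped the lowest chromosomal folds, which start at 1.54. Their median local background was 95.2% of the highest value that 1 fragment per position and strand allows, so a ceiling on input fragments, on a sequence with many copies such as an organelle genome, may have let weak peaks be called there. Enrichment as strong as on the chromosomes, hidden by the ceiling, is argued against: the chromosomal median fold of 4.68 would need 353 ChIP fragments, above the ceiling of 284, whereas the ChIP stood at a median of 44.5% and at most 66.5% of it. The ribosomal RNA peak on chromosome 3, at 282 fragments and a background of 78.4, stood at or just under the same ceiling. No biological explanation was tested.

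RcHzRDP12 had more peaks than RchiOBHm at 14 to 19 fragments (15109 against 13784) and at 20 to 39 (23308 against 15506), and fewer below 14 (4248 against 6557). Below 20 fragments, where most peaks near the threshold lie, it had 0.952 times as many (0.933 to 0.971), a value that pools opposite directions. The local background at RcHzRDP12 peaks was lower at the median, 3.24 against 3.59 fragments, while its lowest value was higher, 3.24 against 3.07. Whether the lower median background adds peaks cannot be told apart from other explanations. Within 1 fragment length (145 bp) of the first base of a sequence started 598 peaks, against 172 in the next 145 bp, for an excess of 3947, so splitting at scaffold ends may add peaks, but how much of the excess it accounts for cannot be told apart, since far ends were not counted. The summed summit fragments of both lists had a ratio of 1.02, over covered lengths of 26.2 and 27.01 Mb and mean pileups of 27.6 and 29.5, which does not test whether fragments were shared between copies of a locus. No explanation was tested for the higher number of peaks with 150 or more fragments, and no biological explanation was tested for either.

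The 148 peaks with 100 or more fragments more than 1 kb from any gene were uniform in width, with a median of 687 bp, against 1077 bp for the 122 such peaks at protein-coding gene ends. Their interquartile range relative to the median was 0.421 times that of the gene-end peaks. Copies of few families of repeated elements could have such uniform widths. Distant peaks of lower height were not compared and no sequence was used, so the widths do not decide this. Their local background was shifted upwards, with a median of 6.35 against 3.70: 63 of them (42.6%, 34.5 to 51.0) were at or below 5.80, the 95th percentile of all peaks, against 100 of the 122 at gene ends. Input-rich sequence may thus contribute to part of them, but since the interval spans an even split, it cannot be told apart whether most are of this kind. Their median fold over this local background was 19.6, against 23.4 for the gene-end peaks, so the raised background does not by itself give their height. They lay on all 7 chromosomes, from 14 on chromosomes 4 and 6 to 43 on chromosome 2, and no biological explanation was tested.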
